A study of Rattus norvegicus and Mus musculus with 27 samples.

How the data were processed

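Brain cortex RNA from 27 animals was sequenced, 18 Sprague-Dawley rats and 9 C57BL/6J mice. Per the labels, RNA was extracted with a Qiagen column kit from tissue frozen on dry ice, and a service company made the libraries. The submitters' processing notes name TopHat, featureCounts 1.4.6 and the builds rn5 for rat and mm10 for mouse, without their settings. How rat and mouse genes were joined into a single table, which annotation was counted and whether strand was used are not given in the sources used here.

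The deposited table, which the submitters named as counts, has 34585 rows and 27 value columns. The value columns are named with the word sample and a number. A column was to be used only where its name matched the labels of 1 sample or of 1 group. Names were compared with the accession, title, description, source name and characteristics of every sample, with punctuation and case removed. No column matched, so all 27 value columns were left unused, and no expression level, fold change, library depth or test is reported. Column order and the values themselves were not taken as evidence of which animal a column came from.

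The column of gene symbols belongs to no animal and was the only part of the table used. Symbols were looked up by exact spelling among mouse symbols of GENCODE M21 and rat symbols of the GRCr8 gene table. No coordinates were taken from GRCr8 because the submitters name another rat build. The 30 gene lists were fixed before the data were examined, and their 913 different entries, some of them alternative spellings of the same gene, were looked up in the table. Both lookups were repeated with the synonyms of the GRCr8 table. The planned tests, among them edgeR's quasi-likelihood test for each contrast, were not run.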

Results

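The series profiled messenger RNA in the brain cortex of 2 rodent models of neurodevelopmental disorders, with and without TAK-418, an inhibitor of the histone demethylase LSD1. The labels describe 27 animals in 9 groups of 3. In rats, the models were offspring exposed before birth to valproic acid (VPA), an antiepileptic drug, and the cortex was taken at 5 or 15 weeks of age. In mice, the offspring had been exposed before birth to poly I:C, a synthetic double-stranded RNA that triggers an antiviral response. Each model had healthy vehicle-treated controls, exposed vehicle-treated animals and exposed TAK-418-treated animals. The 18 rats fell into 6 groups and the 9 mice into 3.

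The design implies 3 comparisons within each model. Exposed against control animals, both on vehicle, ask what the prenatal exposure changed. TAK-418 against vehicle in exposed animals asks what the drug changed. TAK-418-treated exposed animals against controls ask what difference was left. No control animals received TAK-418, so that difference could also hold drug effects unrelated to the exposure. The exposed vehicle-treated animals enter the exposure and drug comparisons with opposite sign, so an apparent reversal can arise with no effect. The rats also allow each effect to be compared between 5 and 15 weeks. The labels do not say whether both ages were processed together, so a batch difference between them cannot be excluded. Only rats received VPA and only mice received poly I:C, so a difference between the exposures cannot be told apart from a difference between the species. No age was found in the labels for the mice, so a difference in age cannot be told apart from these either. None of these comparisons is reported, because 0 of the 27 value columns of the count table had a name that matched a sample or a group in the labels. No gene is therefore described as higher or lower in any group.

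The genes that the table names were examined without their values. Of its 34585 rows, 14040 (40.6%) carried a gene symbol and 20545 (59.4%) carried only the letter G and a number. Whether those numbers stand for particular genes is not given in the sources used here, so a listed gene counted as not named may still be among these rows. Among the named rows, 13836 had a mouse gene symbol of GENCODE M21 and 13533 a rat gene symbol of the GRCr8 table. Both species shared 13518 of them, and 189 were found in neither. With rat synonyms added, 14023 named rows were found among rat genes and 9 in neither species. Mouse genes were looked up without synonyms, so that count is not set against the mouse count.

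All 24 glutamate receptor genes and all 18 genes for GABA-A receptors and GABA transport that had been fixed as lists were named. So were all 28 astrocyte markers and all 25 genes of cholesterol synthesis. Of the other cell type lists, 28 of 31 oligodendrocyte and myelin markers, 26 of 28 microglia markers, 26 of 28 cortical interneuron markers and 26 of 28 markers of excitatory cortical layers were named. Coverage was 16 of 18 for oligodendrocyte precursors and 25 of 28 for endothelial and mural cells. It was 21 of 24 for meningeal cells and fibroblasts, and 18 of 24 (75.0%) for immature neurons and progenitors. Rat synonyms raised the oligodendrocyte and myelin count to 29 and the endothelial and mural count to 26. The other cell type counts above did not change. For other brain structures, 21 of 24 striatal neuron markers and 20 of 21 choroid plexus markers were named. Hippocampal, thalamic and deep-structure markers were named in 30 of 31 cases. With rat synonyms, the striatal count was 23 and the hippocampal, thalamic and deep-structure count was 31. Immediate early genes, which neuronal activity induces, were named in 33 of 34 cases.

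Of 29 genes for the LSD1 complex and for methylation of lysine 4 of histone H3, 19 (65.5%) were named, and rat synonyms added none. These included Kdm1a, which encodes LSD1, and Rcor1, which encodes a corepressor that binds it. Not named were Insm1, Phf21a, Zmym2, Kdm5c and the methyltransferase genes Kmt2a, Kmt2b, Kmt2c, Kmt2d, Setd1a and Setd1b. Of 70 autism risk genes, 56 (80.0%) were named, or 58 with rat synonyms. For the antiviral response that poly I:C triggers, 38 of 44 interferon-stimulated genes (86.4%) were named. Red blood cell genes, fixed as a sign of blood in the tissue, had the lowest coverage of the 30 lists at 5 of 15. Rat synonyms raised that count to 6, and several of the 15 entries were alternative spellings of the same globin genes. Over all lists, 818 of 913 different entries were named, or 828 with rat synonyms. These counts describe row names only and carry no information on expression.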

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

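The alternatives given here were chosen after the header of the table had been seen. A stricter rule required a column name to equal a whole label. It also matched 0 of 27 columns to a sample and 0 to a group. That outcome was fixed in advance, because no label held any of the names, so it is no check on the result. Adding rat synonyms raised the named rows found among rat genes from 13533 to 14023, lowered those found in neither species from 189 to 9, and raised the list entries named from 818 to 828. None of the 209 alternatives planned for the expression results was run, because those results need columns that are tied to animals. No paired analysis was possible because no value column could be tied to an animal. The labels number the animals of each group and do not say that a number marks a shared litter, batch or day. Depth per animal is not analysed here for the same reason.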
